A study of Mus musculus with 4 samples.

How the data were processed

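The data were expression arrays of mouse bone marrow cells cultured with M-CSF for 5 days. The cells were wild type or Jmjd3-/-, unstimulated or given LPS at 100 ng/ml for 4 h, and each of the 4 groups had 1 array. Total RNA was extracted with Trizol, and biotinylated cRNA was prepared with the NuGEN Ovation system and hybridised to Affymetrix arrays. The deposited values are log2 probe set intensities, made by the authors with RMA, as named in the submitters' processing notes. The version, the background model and whether other arrays were processed in the same run are not given in the sources used here. The distributions of the 4 arrays were nearly but not exactly equal, with at most 0.34 between values of the same rank.

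The table held 45101 probe sets, of which 64 were Affymetrix controls and 35890 were listed in the gene annotation. Of the listed probe sets 34945 named 1 gene and 932 named several, and 9160 had no gene name here. Those with 1 gene were used, and for 34741 of them the gene identifier matched the RefSeq gene table of assembly GRCm38.p6, while 204 kept the symbol of the annotation. These gave 18193 genes, each represented by its probe set with the highest mean over the 4 arrays. The median standard deviation between probe sets of the same gene lay between 0.16 and 0.23 over the 4 differences between 2 arrays. Probe sets with no or several gene names were left out of the comparisons, and counts of unnamed ones are in the closing section. The array medians lay between 4.15 and 4.24, and between 14483 and 15561 probe sets per array reached log2 6.

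Choices of comparison, threshold, gene list and alternative were made before the data were examined. There were 5 differences between single arrays or between their responses: LPS in each genotype, genotype in each state, and the difference between the LPS responses. Genes counted when they reached log2 6 in the higher library compared, and a difference of 2-fold or more was counted as higher or lower. With 1 library per group these have no p-value. The LPS effect shared by both genotypes and the genotype effect shared by both states were tested on all 4 libraries with limma 3.58.1 in R 4.3.3, an additive model with intensity trend and 1 residual degree of freedom. It took the 9385 genes at or above log2 6 in a library, with a prior of 3.84 degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p below 0.05, and words such as rose and fell are kept for these. At an unadjusted p below 0.05 there were 4221 genes for LPS and 2287 for genotype. Agreement between differences was described by Pearson and Spearman correlation across genes, and the third split of the 4 libraries into pairs served as a size reference.

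There were 24 gene lists with 545 entries, of which 498 matched a gene with 1-gene probe sets. They were H3K27 demethylases and Polycomb genes, inflammatory cytokines and enzymes, chemokines, NF-kB regulators, interferon-stimulated genes, alternative activation, macrophage identity, Toll-like receptor pathway, cell cycle, cholesterol, LXR and PPAR targets, MHC class II, glycolysis and hypoxia, immediate early and heat shock, Hox and developmental genes, genes near Kdm6b, sex-linked and housekeeping genes. The others were markers of granulocytes and their precursors, dendritic cells, T, B and NK cells, erythroid cells and megakaryocytes, mast cells with basophils and eosinophils, and stromal cells. List medians, given for 3 or more members past the floor, were set against 10000 random lists of the same size matched on mean expression in 20 bins, as a description. A marker of cells present in 1 group passes the floor there because it differs, so some medians of marker lists are also given over all measured members. Spreads of medians come from 1000 bootstrap resamples. The test was also adjusted over each list alone. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

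Genes were named by a rule. Kdm6b was given in every library, and Arg1, Irf4, Chil3, Retnla and Mrc1 in every comparison. List members with the largest absolute difference served as examples, and outside the lists the 10 highest and 10 lowest genes of each difference could be named. For shared effects these were ranked by the smaller of the 2 absolute differences. Further list members, such as Ciita, Csf1r, Adgre1, Csf1, S100a9 and Jarid2, and the genes with opposite differences were chosen after their values were seen. Some genes of the lists are not reported here.

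The limma test was tested on simulated data, with noise drawn from the fitted spread and 200 of 9385 genes changed. For LPS it recovered 12% of genes changed by log2 1, 84% at log2 2, 90% at log2 3 and 98% at log2 4, with 13 false calls. For genotype these were 6%, 78%, 88% and 96%, with 8 false calls. The simulated noise was independent, with no effect of the other factor and no true difference between the LPS responses. Fewer genes were changed than limma called in the data, so these rates need not hold for the data. The list percentiles were tested with 25 lists shifted by log2 1 and 25 not shifted, and 25 and 2 of them fell outside the central 95%. Alternatives tried were median centring, quantile normalization, no floor or a floor of log2 8, offsets of 16 and 64 on the linear scale, thresholds of 1.5-fold and 3-fold, the mean of a gene's probe sets, and leaving out probe sets marked as less specific. For limma, fits with no intensity trend, with robust moderation and without the other factor were added.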

Results

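Gene expression was measured in bone marrow-derived macrophages, cells grown from mouse bone marrow for 5 days with the growth factor M-CSF. The cells were labelled wild type or Jmjd3-/-, called knockout here. Jmjd3 is the histone H3 lysine 27 demethylase encoded by Kdm6b. Each genotype was studied unstimulated and after 4 h with 100 ng/ml lipopolysaccharide (LPS), the cell wall component of Gram-negative bacteria that activates Toll-like receptor 4. The 4 groups held 1 array each, so no single difference between 2 arrays has a replicate check. Expression levels are log2 RMA values and differences are on that scale, and folds are 2 raised to the difference. Where the lower array lay under log2 6, the size of a difference rests on a background reading. The arrays were similar in overall level, with medians of 4.19 for unstimulated wild type, 4.16 for wild type with LPS, 4.24 for unstimulated knockout and 4.15 for knockout with LPS. Between 32.1% and 34.5% of probe sets reached log2 6, the floor used for comparisons. The 3' minus 5' difference of the beta-actin control lay between 0.65 and 0.75 on the 4 arrays, and that of the Gapdh control between 0.73 and 0.93.

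Kdm6b was examined first, as the targeted gene. Its brightest probe set read 10.33 in unstimulated and 11.23 in LPS-treated wild-type cells, against 9.82 and 10.82 in the knockout. The knockout minus wild type difference was thus -0.51 without and -0.41 with LPS, and this probe set, of a class marked as less specific, was above the floor on all 4 arrays. A dimmer probe set, under the floor on 3 of the 4 arrays, was higher in the knockout by 0.64 and 0.85, and the dimmest stayed below log2 6 throughout. The part of the gene that was deleted is not given in the sources used here, so these probe sets do not settle whether the labels are right. Kdm6b itself rose with LPS on its brightest probe set, by 0.95 over both genotypes (limma, Benjamini-Hochberg adjusted p = 0.0165, higher in both). The dimmer probe set differed with LPS by 0.51 in wild type and 0.72 in the knockout, and the dimmest by 0.97 and -0.31. Of 11 H3K27 demethylase and Polycomb genes, a list that includes Kdm6b, Jarid2 also rose with LPS (1.23), while Ezh2 and Eed fell (-1.03 and -0.83). Adjusted over the list alone, 2 rose and 4 fell with LPS, and none of the 11 passed between genotypes, at either adjustment.

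The LPS response shared by both genotypes was the largest contrast in the data. Il6 rose by 7.95 and Il12b by 7.43, both encoding inflammatory cytokines, and Nos2, which encodes inducible nitric oxide synthase, by 6.03. The chemokine gene Cxcl11 rose by 7.78, Ch25h by 6.12, and Il10, an anti-inflammatory cytokine, by 5.69. Large decreases were in Arhgap19 (-5.24), Pald1 (-4.73), Rnf144b (-4.02) and Cnr2 (-3.80), the gene of cannabinoid receptor 2. Across 9385 genes, 1054 rose and 1769 fell in the additive model of genotype and LPS. Il6 had a standard error of 0.25 (limma, Benjamini-Hochberg adjusted p = 0.00177, higher in both genotypes).

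By gene group, 22 of 25 inflammatory cytokine and enzyme genes rose with LPS, none fell and 3 did not pass (24 rose adjusted over the list alone). Of 36 interferon-stimulated genes, 35 rose and 1 did not pass (36 rose adjusted over the list alone). The largest were Mx2 (5.88), Cmpk2 (5.81), Ifit1 (5.67) and Oasl1 (5.57). NF-kB and feedback regulators rose in 23 of 27 cases (27 adjusted over the list alone), led by Cd40 (5.15), Traf1 (4.87) and Socs3 (3.67). Of 20 chemokine and chemokine receptor genes, 13 rose, 2 fell and 5 did not pass (16 and 2 adjusted over the list alone), with Cxcl9 at 6.22 and Ccl5 at 5.77, and the genes that fell were the receptors Ccr2 (-1.57) and Cx3cr1 (-2.11). In the Toll-like receptor pathway 12 of 22 rose and 1 fell (the same counts adjusted over the list alone), with Tlr3 at 3.05, the adaptor gene Myd88 at 1.76 and Tlr13 at -1.40.

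Cell cycle genes went the other way: 25 of 34 fell with LPS and 1 rose (28 and 1 adjusted over the list alone). Kif20a fell by 2.40, Cenpa by 2.36 and Ccna2 by 2.20, and the gene that rose was Cdkn1a (0.82), an inhibitor of cell cycle progression. In the glycolysis and hypoxia list 6 of 22 rose and 1 fell (the same counts adjusted over the list alone), led by Pfkfb3 (2.27), which drives glycolytic flux. Of 15 cholesterol synthesis and uptake genes 4 fell (4 adjusted over the list alone), including Dhcr7 (-2.32) and Stard4 (-1.91). Of 15 LXR and PPAR targets 4 fell and 1 rose (the same counts adjusted over the list alone), with Scd2 at -2.23, the cholesterol exporter gene Abca1 at -1.38 and Srebf1 at 1.12. Among 32 macrophage identity genes 5 rose and 9 fell (6 and 10 adjusted over the list alone). Cebpa, a myeloid transcription factor, fell by 3.32 and Csf1r, the M-CSF receptor, by 0.80, whereas Cebpb rose by 1.97. Of 18 immediate early and heat shock genes 2 rose and 2 fell (the same counts adjusted over the list alone), Junb rising by 1.49 and Jun falling by 1.08. Among 31 alternative activation genes Ccl22 rose by 4.86, while Pparg (-1.78), Stab1 (-1.03), Igf1 (-0.60) and Clec7a (-0.58) fell (0 rose and 2 fell adjusted over the list alone). Of 12 MHC class II antigen presentation genes the costimulatory genes Cd86 (3.07) and Cd80 (2.17) rose and 3 fell, Ciita at -1.03 (the same counts adjusted over the list alone). Of 7 dendritic cell markers 4 rose, Ccr7 (3.78), Tcf4 (1.21), Dpp4 (1.17) and Bst2 (1.10). Of 8 mast cell, basophil and eosinophil markers Hdc (4.02) rose and Siglecf (-1.21) fell, and of 4 erythroid and megakaryocyte markers Car2 (2.41) rose (all the same counts adjusted over the list alone). Of 13 granulocyte markers Mmp8 (-1.08) fell (0 adjusted over the list alone), and none of 17 stromal and 8 T, B and NK markers passed, at either adjustment. Housekeeping genes fell in 2 of 16 cases (1 adjusted over the list alone) and genes near Kdm6b in 6 of 17 (6 adjusted over the list alone), and none rose. The p-values rest on 1 residual degree of freedom and assume additive effects. The spread they measure is the difference between the LPS responses of the 2 genotypes, moderated by the prior. A gene whose response differs between the genotypes is thus less likely to pass. Nothing in the sources used here says that the samples came from separate animals or cultures. Fitted without the genotype term, 267 genes passed in place of 2823.

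**Figure D1:**
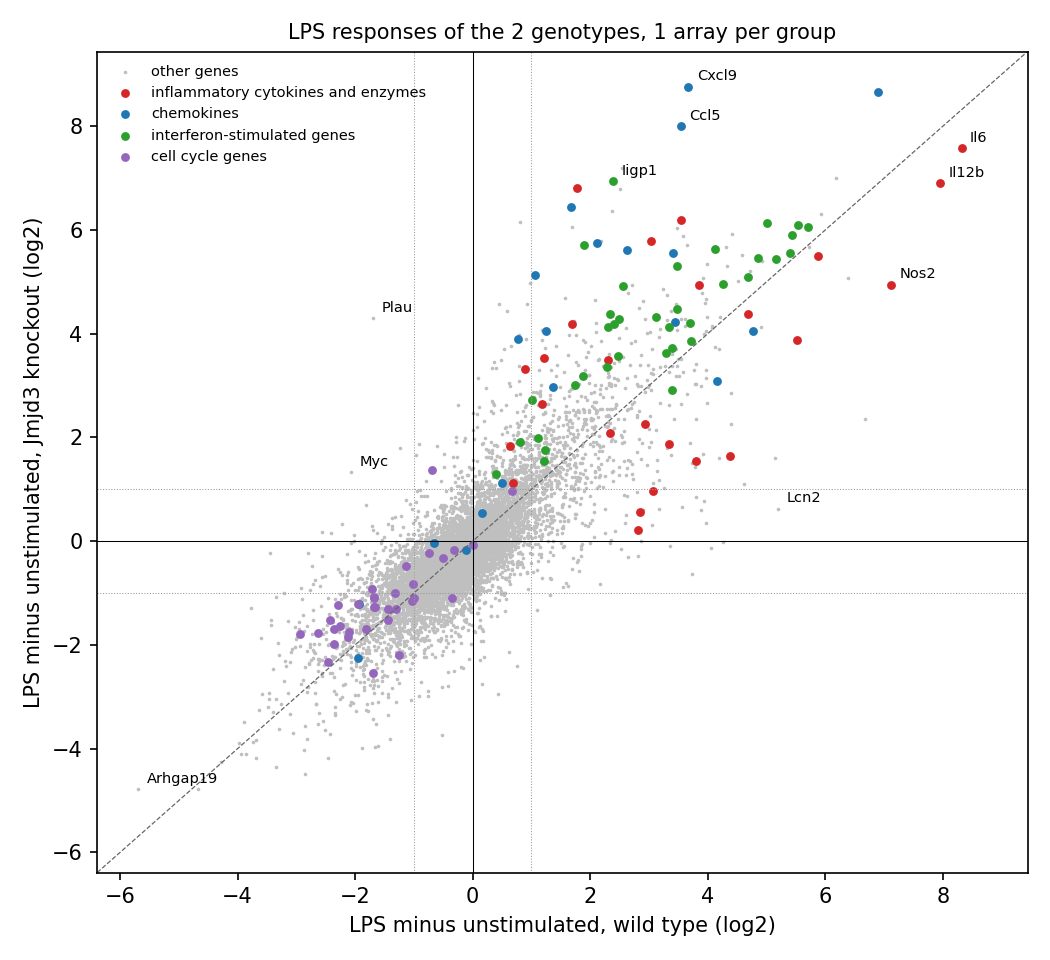
LPS minus unstimulated difference (log2) of each gene past the floor in wild-type (x axis) and Jmjd3 knockout cells (y axis), 1 array per group, with 4 gene lists in colour, dotted lines at 2-fold and a dashed line at equal responses. Interferon-stimulated genes and chemokines such as Iigp1, Ccl5 and Cxcl9 lie above the dashed line, and most cell cycle genes lie in the lower left, with Cdkn1a and Ccnd1 among the exceptions.

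In wild-type cells alone, Il6 read 13.12 with LPS, Il12b 11.58 and Nos2 10.87, against 4.80, 3.63 and 3.75 unstimulated, all under the floor. Other large increases were in U90926 (6.68), Hamp (6.39), which encodes the iron regulator hepcidin, Ifit1bl1 (6.18) and Il33 (5.73). Among the lowest values were those of Arhgap19 (-5.69), Pald1 (-4.68), Rab3il1 (-3.97), Slc43a2 (-3.90) and Kazald1 (-3.77). The median of the cytokine list was 3.04, that of interferon-stimulated genes 3.20, that of chemokines 1.51 and that of NF-kB regulators 1.58, each at percentile 100 of 10000 random lists matched on size and expression. The cell cycle median was -1.67 (percentile 0) and the cholesterol list's -0.77 (percentile 0.95). Of 30 alternative activation genes 6 were 2-fold or more lower, Socs2 (-2.22), Myc (-2.06), Pparg (-1.42), Stab1 (-1.17), Cdh1 (-1.13) and Klf4 (-1.09), and 1, Ccl22 (2.54), was higher. Arg1 differed by -0.72, Chil3 by -0.10, Retnla by -0.09, Mrc1 by -0.47 and Irf4 by -0.28. Of 7 mast cell, basophil and eosinophil markers 4 were 2-fold or more higher, Hdc at 3.46 and Cpa3 at 1.99, Siglecf differed by -0.77, and the median was 1.54 (0.74 over all measured members). Dendritic cell markers had a median of 1.09 (0.25 over all measured members), granulocyte markers of 0.70 (0.17) and stromal markers of 0.53 (0.46). In all, 851 of 8627 genes were 2-fold or more higher and 1233 lower, with no test, but with a floor of log2 8 these counts were 645 and 696, so the excess of lower genes depends on the setting.

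In Jmjd3 knockout cells chemokine and interferon-inducible genes were among those with the highest values. Cxcl9 read 12.11 with LPS, Cxcl11 12.62 and Ccl5 13.56, against 3.34, 3.96 and 5.57 unstimulated, all under the floor, and these are chemokines that attract T cells among other leukocytes. Il6 was higher by 7.58, Ccl22 by 7.19, the interferon-inducible GTPase genes Iigp1 by 6.95 and Gbp2b by 6.79, and Acod1, the itaconate-producing enzyme gene, by 6.81. Among the lowest values were Arhgap19 (-4.78), Pald1 (-4.78), Slc46a3 (-4.48), Sesn1 (-4.35) and Cebpa (-4.18). The list medians were 4.24 for interferon-stimulated genes, 4.05 for chemokines, 3.70 for cytokines and 2.25 for NF-kB regulators, each at percentile 100. Cell cycle genes had a median of -1.25 (percentile 0). In the alternative activation list 7 of 25 genes were 2-fold or more higher and 1 lower (median -0.01). Irf4 was higher by 1.91 and Retnla, below the floor on both knockout arrays, by 0.88, while Arg1 (-0.17), Chil3 (-0.01) and Mrc1 (-0.38) differed little. Here 1006 of 9122 genes were 2-fold or more higher and 1415 lower, again without a test, against 778 and 783 with a floor of log2 8 and 794 and 745 with 64 added to the linear values.

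The LPS responses of both genotypes, over 9385 genes past the floor, correlated at r = 0.818 (Spearman rho = 0.789), across genes that are not independent replicates and from differences that share no library. There were 1561 genes that reached 2-fold the same way in both, 679 of them higher and 882 lower, against 5 that reached 2-fold in opposite directions (Galnt3, Ifngr2, Myc, Plau and Rnase6).

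Between the unstimulated arrays of both genotypes, granulocyte and collagen genes stood among the highest values in the knockout, and chemokine genes among the lowest. Ngp and Camp, which encode neutrophil granule proteins, read 11.82 and 11.66 in the knockout and 3.87 and 4.08, under the floor, in wild type, and Mpo, the myeloperoxidase gene, 11.64 and 4.65. The collagen genes Col1a1 and Col3a1 read 12.35 and 11.22 against 5.84 and 4.83, also under the floor, with higher values for Has2 (6.43), Myl9 (6.19), Thbs2 (6.17) and Mgp (6.08) as well. Among the lowest in the knockout were Rnase2a (-7.33), Ly6i (-6.91), Cxcl3 (-6.89), Plet1 (-6.84), Ccl17 (-6.63), Ccl1 (-5.97), F3 (-5.71) and Ccl22 (-5.52). Arg1, the arginase 1 gene used as a marker of alternative (M2) activation, was 20.3-fold lower and Irf4, a transcription factor gene of the same list, differed by -3.88, from 9.85 to just under the floor. Chil3 differed by -1.02, Retnla by -2.42 and Mrc1 by 0.24.

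Of 31 alternative activation genes past the floor, 18 were 2-fold or more lower in unstimulated knockout cells and 5 higher (median -1.55, percentile 0). Chemokines had a median of -2.77 (percentile 0), with 11 of 18 lower, among them Ccl5 (-4.46) and Cxcl9 (-4.35). Of the cytokine list 8 of 16 were lower and 3 higher, with Acod1 at -5.16, Csf2 at -5.02 and Lif at 3.54. Interferon-stimulated genes had a median of -0.88 and MHC class II genes of -1.97 (both at percentile 0). The marker lists moved beside these groups: granulocyte precursors had a median of 5.76, and stromal cells of 5.23, both at percentile 100, and dendritic cells of -1.76 (-0.20 over all measured members). T, B and NK markers had a median of -0.87 (-0.39 over all measured members) and mast cell, basophil and eosinophil markers of -1.41 (-0.94). The 3 erythroid and megakaryocyte markers past the floor, Car2, Vwf and Ppbp, were all lower (-3.05, -1.14 and -3.09), and the median over all measured members was -0.14. Macrophage identity and housekeeping genes had medians of 0.02 and -0.01 (percentiles 79.9 and 59.1), and of 34 cell cycle genes 9 were 2-fold or more higher and none lower (median 0.77, percentile 100). In this untested comparison 863 of 9045 genes were 2-fold or more higher in the knockout and 519 lower.

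With LPS, values highest in the knockout included Ngp (7.62), Ifi202b (7.42), an interferon-inducible gene, Mpo (6.86), Has2 (6.09), Trim12a (5.98), Serpinh1 (5.84) and Gzme (5.66). Values lowest in the knockout included Rnase2a (-6.83), Acpp (-6.20), Clec4n (-5.88), Ccl1 (-5.80), Plet1 (-5.76), Epha4 (-5.43) and the granzyme gene Gzmb (-5.38). Arg1 remained 13.9-fold lower and Irf4 was 3.24-fold lower, Retnla differed by -1.45, Chil3 by -0.94 and Mrc1 by 0.32. The cytokine genes Il12a (-3.21), Il23a (-2.85) and Csf3 (-2.76) and Nos2 (-2.79) were lower, Il6 differed by -1.44 and Tnf by -0.56, and 10 of 25 list members were 2-fold or more lower (median -0.56, percentile 0). Chemokines had a median of -0.04 (percentile 24.6) and interferon-stimulated genes of 0.15 (percentile 98.5). Alternative activation genes (-0.86) and MHC class II genes (-1.98) were again at percentile 0, and cell cycle genes (1.11) again at percentile 100. Glycolysis genes were at percentile 0 with LPS (-0.34) and at 18.5 without (-0.11). Granulocyte and stromal markers again had high medians (5.25 and 4.70), and the T, B and NK list and the mast cell, basophil and eosinophil list low ones (-2.80 and -2.80). Most of the low members passed the floor on wild-type arrays alone, and over all measured members these medians were -0.49 and -1.11. Overall counts were 842 of 8630 genes 2-fold or more higher and 488 lower, with no test.

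Across both states, the genotype effect was tested in the additive model, where 600 of 9385 genes were higher in the knockout and 293 lower. Ngp rose by 7.78, Mpo by 6.93, Has2 by 6.26, Col3a1 by 6.17 and Prtn3 by 5.74 in the knockout libraries, and Rnase2a fell by 7.08, Plet1 by 6.30, Ccl1 by 5.89, Ccn3 by 5.56, Clec4n by 5.30 and Mgl2 by 4.84. Arg1 fell by 4.07 with a standard error of 0.19 (limma, Benjamini-Hochberg adjusted p = 0.00131, lower in both states). Irf4 fell by 2.79 with a standard error of 0.53 (limma, Benjamini-Hochberg adjusted p = 0.0417), and Chil3 by 0.98 (limma, Benjamini-Hochberg adjusted p = 0.00535). Retnla at -1.94 and Mrc1 at 0.28 did not pass (limma, Benjamini-Hochberg adjusted p = 0.0607 and 0.251).

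Of 31 alternative activation genes 15 fell, 4 rose and 12 did not pass (17 and 5 adjusted over the list alone). Beside those named, Ccl17 (-4.64), Ccl24 (-4.51), Pdcd1lg2 (-4.15), which encodes PD-L2, and Cdh1 (-3.77), the E-cadherin gene, fell. The scavenger receptor gene Cd163 (4.57), the folate receptor gene Folr2 (2.36), F13a1 (2.31) and Stab1 (1.39) rose. Of 12 MHC class II antigen presentation genes 10 fell and none rose (11 fell adjusted over the list alone), including H2-Eb1 (-2.81), H2-DMb2 (-2.77), H2-Aa (-2.62), Ciita, the class II transactivator (-1.88), and Cd74 (-1.42). In the cytokine list 2 fell and 2 rose of 25 (4 and 4 adjusted over the list alone): F3 (-4.55) and Csf2 (-4.28), the GM-CSF gene, were lower, Lif (2.81) and Csf1 (1.53), the M-CSF gene, higher. Of 20 chemokine genes 5 fell and 1 rose (6 and 1 adjusted over the list alone), Cxcl3 at -4.85, Ccr1 at -2.36 and Cx3cr1 at 3.05. Cell cycle genes rose in 9 of 34 cases and none fell (17 rose adjusted over the list alone), as in Kif11 (1.72) and Ccnb2 (1.56). Among 32 macrophage identity genes 6 fell and 3 rose (10 and 6 adjusted over the list alone). Marco (-2.33) and Tlr4, the LPS receptor gene (-1.42), were lower and Apoe (2.65) higher, while Csf1r differed by 0.06 and Adgre1 by 0.53 without passing.

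Markers of other cell types changed beside these groups. Stromal markers rose in 15 of 17 cases (15 adjusted over the list alone, where 1 also fell), with Col1a1 at 6.04 and Sparc at 5.24, and Dcn, a proteoglycan gene, did not pass (0.84). Granulocyte and precursor markers rose in 11 of 13 (12 adjusted over the list alone), S100a9 at 5.68, while Mmp8 fell by 2.92 at both adjustments. Of 8 T, B and NK markers 3 fell and 1 rose (5 and 2 adjusted over the list alone): the T-cell receptor complex genes Cd3e (-3.06), Cd3d (-2.54) and Cd3g (-3.33) were lower, and Ebf1 (3.53) higher. Of 8 mast cell, basophil and eosinophil markers 4 fell and 1 rose (6 and 1 adjusted over the list alone), with Fcer1a at -3.75, Mcpt8 at -2.07 and Prg2 at 4.91. Of 7 dendritic cell markers 3 fell and 1 rose (5 and 2 adjusted over the list alone), Ccr7 at -2.69 and Itgax at -2.25. None of 4 erythroid and megakaryocyte markers passed over all genes (3 fell adjusted over the list alone). Xist, the non-coding RNA of the inactive X chromosome, rose by 2.45, and the Y-linked genes Eif2s3y (-0.04), Kdm5d (-0.08) and Uty (-0.43) did not pass.

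In most of the remaining lists few genes passed between genotypes. None of 16 housekeeping genes and none of 27 NF-kB regulators passed, at either adjustment, where limma called 893 genes in all. The test asks for an effect shared by both states, so a difference in 1 state alone widens its spread. Without LPS, NF-kB regulators had a median genotype difference of -0.30 (percentile 0.24), and 4 of 25 were 2-fold or more lower and 1 higher. Interferon-stimulated genes had 15 of 34 lower and 1 higher in that state. With LPS, neither list had a member 2-fold or more lower, and each had 1 higher. Of 36 interferon-stimulated genes 1, Isg20 (1.15), rose (0 adjusted over the list alone), and of 22 Toll-like receptor pathway genes 1, Tlr4, fell at both adjustments. Hif1a (-0.71) and Slc2a1 (-0.72) fell among 22 glycolysis and hypoxia genes (7 adjusted over the list alone), and Mvd (-1.78) among 15 cholesterol genes (1 adjusted over the list alone). Scd1 (1.94), Angptl4 (2.09) and Fabp4 (0.94) rose among 15 LXR and PPAR targets (4 rose and 2 fell adjusted over the list alone). Hspb1 (3.65) rose and Hsph1 (-0.63) fell among 18 immediate early and heat shock genes (2 and 2 adjusted over the list alone). Of 3 Hox and developmental genes past the floor, Bmp2 (1.62) rose (2 adjusted over the list alone). Of 17 genes near Kdm6b on chromosome 11, Tmem88 (3.67) rose and none fell (2 and 1 adjusted over the list alone). These counts depend on settings: 461 of 6331 tested genes passed with a floor of log2 8 and 530 of 7819 with the mean of each gene's probe sets. Without the LPS term 111 of 9385 passed, in place of 893. Any difference between the animals or cultures is confounded with genotype.

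**Figure D2:**
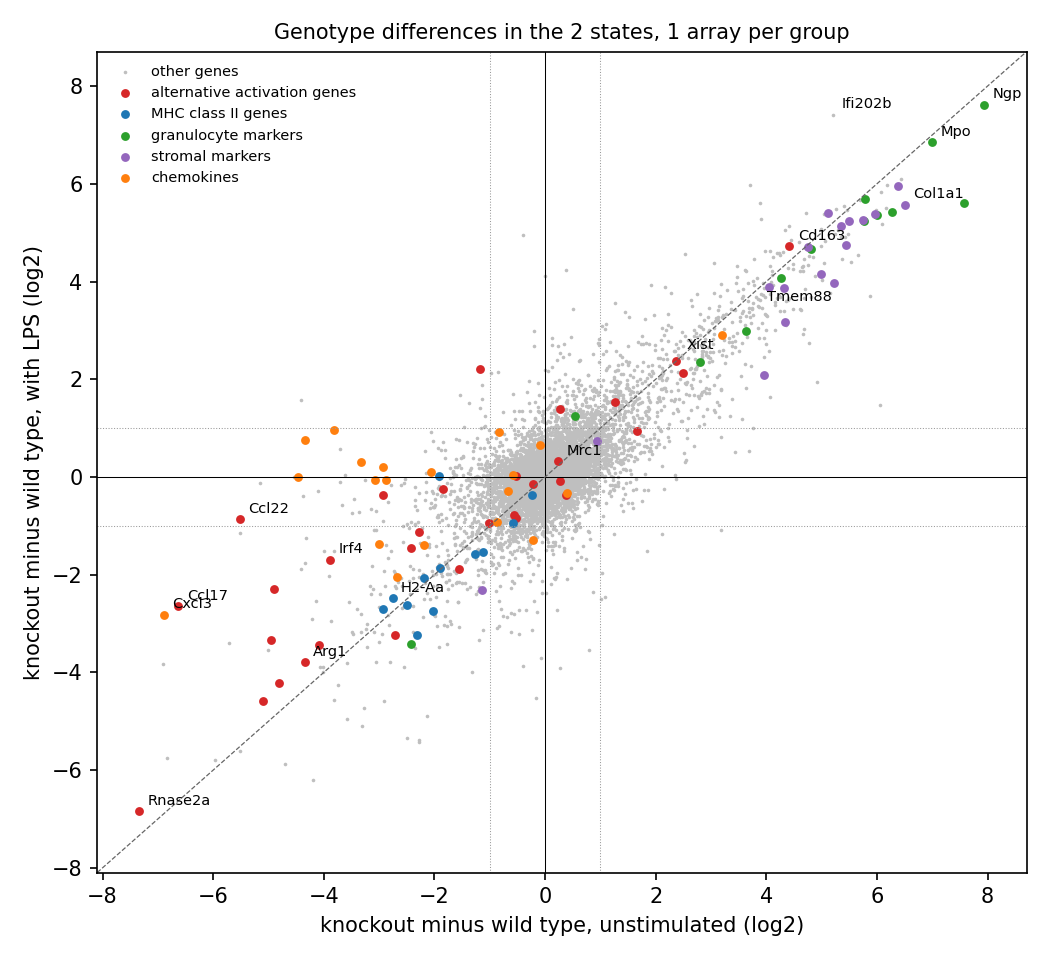
Knockout minus wild type difference (log2) of each gene past the floor without (x axis) and with LPS (y axis), 1 array per group, with 5 gene lists in colour, dotted lines at 2-fold and a dashed line at equal differences. Most granulocyte and stromal markers lie at the upper right (not Mmp8 and Thy1), most MHC class II and several alternative activation genes at the lower left, and chemokines such as Ccl5 (-4.46 and -0.01) and Cxcl9 lie at the left near 0 on the y axis, with Cxcl3 lower and Cx3cr1 at the upper right.

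Genotype differences of both states correlated at r = 0.783 over 9385 genes (Spearman rho = 0.582), again across genes. Of these, 619 were 2-fold or more higher in the knockout in both states and 259 lower, and 19 were 2-fold apart in opposite directions. As a size reference, the third way of splitting the 4 libraries into pairs, unstimulated wild type with LPS knockout against the others, left 103 genes 2-fold higher and 78 lower. The LPS split gave 935 and 1315, and the genotype split 825 and 444.

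**Figure D3:**
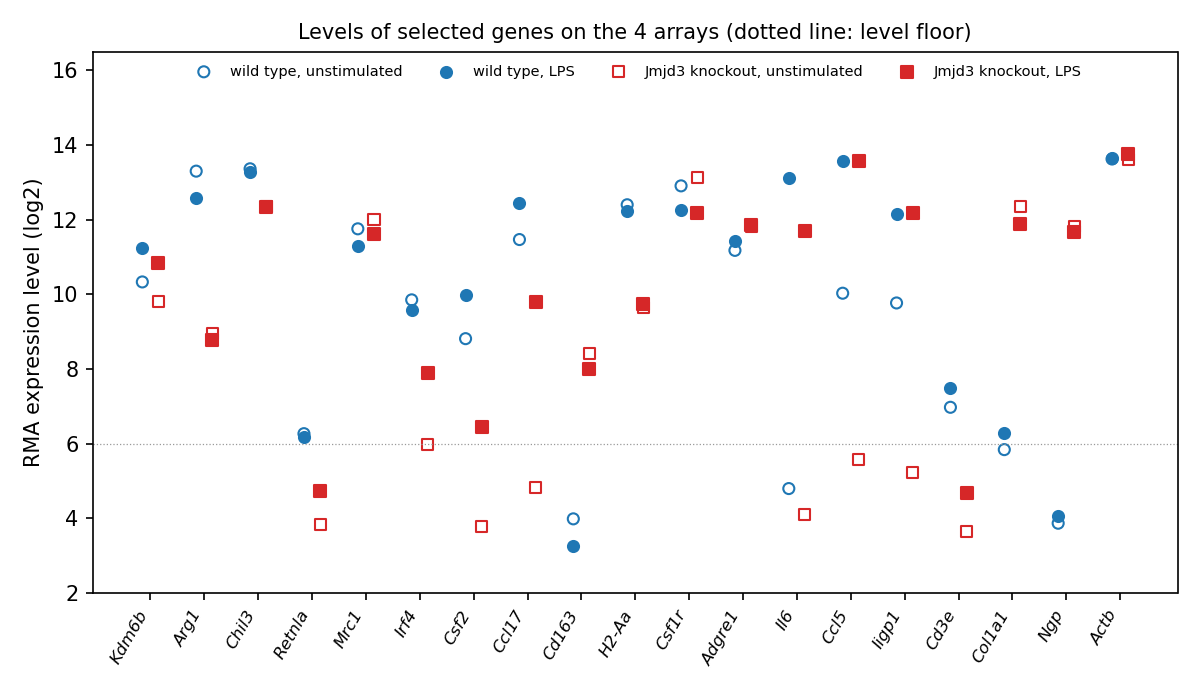
RMA expression level (log2) of 19 genes on each of the 4 arrays, circles for wild type and squares for Jmjd3 knockout, open without and filled with LPS. Arg1 stood at 13.30 and 12.58 in wild type and 8.96 and 8.79 in the knockout, while Ccl5 reached 13.57 and 13.56 with LPS from 10.03 and 5.57.

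The difference between the LPS responses is the genotype difference with LPS minus that without, so a low value before LPS in the knockout raises it by construction. Ccl5 stood at 5.57 in unstimulated knockout and 10.03 in unstimulated wild-type cells, and at 13.56 and 13.57 with LPS, so its response was larger by 4.46 in the knockout. Cxcl9 (5.09), Acod1 (5.04), Ccl12 (4.78), Ccl22 (4.65), Iigp1 (4.55), Cfb (4.38), a complement gene, and Gbp2b (4.29) also had larger responses in the knockout. Plau, the urokinase gene, was lower with LPS in wild type (-1.70) and higher in the knockout (4.30), and BC023105 was higher mainly in the knockout (6.16 against 0.81). The response was smaller in the knockout for Lcn2 (-4.57), a neutrophil granule gene already at 11.27 without LPS, and for Nts (-4.37), U90926 (-4.33), Serpinb1a (-4.27), Zfp558 (-4.20), Cav1 (-3.55) and Fst (-3.52). The knockout response minus the wild-type response was 2.19 for Irf4, 0.97 for Retnla, 0.55 for Arg1, 0.08 for Chil3 and 0.09 for Mrc1. With LPS, Arg1 differed by -0.72 in wild type and -0.17 in the knockout, Chil3 by -0.10 and -0.01, and Mrc1 by -0.47 and -0.38. None of these differences reached 2-fold, and with 1 array per group they have no replicate check.

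The list medians of this difference were 1.68 for chemokines, 0.95 for interferon-stimulated genes, 0.52 for alternative activation genes and 0.43 for NF-kB regulators, each at percentile 100. The cytokine list split, with 10 of 25 larger in the knockout by 2-fold or more and 9 smaller. Il1a (2.75) and Il1b (2.64) were among the former, and Il12a (-2.73), Csf3 (-2.61), Inhba (-2.28) and Nos2 (-2.17) among the latter. Mast cell, basophil and eosinophil markers (-1.10, and -0.53 over all measured members) and stromal markers (-0.49, percentile 0.1) had lower medians, beside granulocyte markers at -0.45 (percentile 0.33). Only 10 of these 17 stromal and 6 of these 13 granulocyte markers passed the floor on a wild-type array. For the rest the wild-type response is a background reading, so these 2 medians do not show a smaller LPS response in the knockout. Of the 679 genes 2-fold or more higher with LPS in both genotypes, 151 were 2-fold or more lower in unstimulated knockout cells and 44 higher, against 96 and 53 with LPS. In total the knockout response minus the wild-type response was positive by 2-fold or more for 487 of 9385 genes and negative for 444. A weaker decrease in the knockout counts as positive, as for Kazald1 (-3.77 in wild type and -1.28 in the knockout). The balance depends on the setting (335 and 209 with a floor of log2 8, 596 and 657 with no floor). With 1 library per group this difference leaves no residual degrees of freedom and was not tested.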

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

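The tests of housekeeping, macrophage, lymphoid, mast cell, stromal, granulocyte and Xist values and of the genes around Kdm6b were chosen after the result was seen, and those around Ifi202b and Trim12a before.

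Genes stood out when the difference ran in opposite directions in 2 groups, which was not tested because each group had 1 library. There were 5 genes with LPS responses of 2-fold or more in opposite directions in the 2 genotypes (Galnt3, Ifngr2, Myc, Plau and Rnase6) and 19 with genotype differences of 2-fold or more in opposite directions in the 2 states. The knockout response minus the wild-type response was 3.40 for Myc, 5.99 for Plau, 2.13 for Egr3 and 2.49 for Kazald1. It was -3.55 for Cav1, -3.37 for Cd28, -3.52 for Fst and -4.27 for Serpinb1a.

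Signals also appeared outside the compared genes. Of 1397 probe sets with no gene name here past the floor, 122 were 2-fold or more apart between genotypes the same way in both states, and 293 with LPS the same way in both genotypes. The bioB hybridisation control on the knockout LPS array was 0.58 above the mean of the other arrays. It read 10.8 on both unstimulated arrays, 11.1 on the wild-type LPS array and 11.5 on the knockout LPS array, so it was higher with LPS in both genotypes.

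Alternative activation and MHC class II genes were lower in the knockout libraries, with median shared effects of -1.05 (bootstrap standard deviation 0.65) and -2.01 (0.40), and the loss of Jmjd3 stays open as an untested explanation. The median of the housekeeping genes was 0.039 (0.106). It cannot decide on array scaling or RNA quality, because normalization gave the 4 arrays nearly equal distributions and so removes a shift common to most genes. The 3' minus 5' differences lay between 0.65 and 0.75 for the beta-actin control and between 0.73 and 0.93 for the Gapdh control. The median of the macrophage identity genes was -0.013 (0.127), over 32 genes of which 6 fell and 3 rose. It argues against a dilution of macrophages by other cells in the knockout cultures as large as the 2 list medians. This holds only if those other cells do not express the same genes, which was not tested. A smaller dilution remains open. Csf2-expressing lymphoid or mast-like cells in the wild-type cultures remain open. Of the T, B, NK, mast cell, basophil and eosinophil markers past the floor 68.8% were 2-fold or more lower in the knockout in both states. This share met the bound written for this explanation, but markers seen on wild-type arrays alone pass the floor because they differ. Over all 33 measured markers, which the written bound did not name, the share was 42.4%, and with this added requirement the test does not decide. Csf2 fell by 4.28, and among these markers Gata2 stood at 7.78 and 8.77 in wild type against 5.96 and 5.73 in the knockout and Cd3e at 6.97 and 7.49 against 3.65 and 4.69, but Hdc (0.35), Blnk (0.20), Prg2 (4.91), Ebf1 (3.53) and Cd79b (1.98) were not lower.

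Stromal and granulocyte precursor transcripts were higher in the knockout libraries. Stromal cells in the knockout cultures remain open, with 88.2% of stromal markers past the floor (83.3% of all measured) 2-fold or more higher in both states and Sparc at 12.71 and 12.56 against 7.36 and 7.43 in wild type, although Dcn did not pass and Thy1 was lower (-1.15 and -2.31). Granulocyte precursors remain open with 84.6% of their markers higher (78.6% of all measured), S100a9 at 13.44 and 13.51 against 7.44 and 8.15, although Mmp8 fell by 2.92. A mixture of female and male cells in the knockout libraries also remains open, since the smallest difference over the Xist probe sets was 2.40 while the Y-linked genes lay within 2-fold. A change within macrophages through the loss of Jmjd3 was not tested.

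Genes beside Kdm6b and single genes of other regions differed between genotypes. Sequence or strain differences around the Kdm6b locus were tested by counting, among the 50 nearest measured genes, those 2-fold or more apart the same way in both states. This gave 5 (Hs3st3b1, Tmem88, Dnah2, Asgr2 and Mgl2), against a median of 4 and a 95th percentile of 9 in other windows. Tmem88 and Dnah2 belong to the list of genes near Kdm6b. A count over 50 genes cannot show a difference confined to a few genes beside Kdm6b. A strain block around Ifi202b gave 7 and a strain block around Trim12a gave 3 by the same count, and 23.9% and 77.2% of other windows had as many, against 49.7% for Kdm6b. These counts leave all 3 open, because each lies within the spread of other windows. The bound written beforehand against a strain block was a count at or below the median, which the 3 around Trim12a met, and the requirement that it do so by more than its counting spread was added after that count was seen.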

How the results depend on the processing

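No alternative was added after a result was seen. Of 98 values and counts that answer a comparison 65 stayed within their bounds, 29 moved and 4 were weaker, and of 460 list medians 423 stayed, 36 moved and 1, outside the central 95% of random lists, reversed. In all 26 medians had the other sign than in the main setting, and the other 25 of them lay within that central range, for example T, B and NK markers with LPS in the knockout (-0.80, and 0.07 over all measured members). Of 748 values of named genes 543 stayed and 205 moved, none with a turn of sign in a called value. These exclude Kdm6b, whose difference turned sign between probe sets (below). Genes at or past the size threshold numbered, in the main setting, 2084 for LPS in wild type, 2421 for LPS in the knockout, 1382 for genotype unstimulated, 1330 for genotype with LPS, 931 for the response difference and 181 for the third split. With a floor of log2 8 the counts in that order were 1341, 1561, 777, 687, 544 and 114, where fewer genes were compared. With 64 added to the linear values they were 1292, 1539, 876, 813, 437 and 62, and with 16 added the third split gave 107, as an offset shrinks differences of dim genes. With a 1.5-fold threshold they were 3780, 4269, 2689, 2361, 2408 and 640, and with 3-fold 974, 1159, 773, 752, 320 and 35, by construction. More genes were lower than higher with LPS in the main setting (1233 against 851 in wild type, 1415 against 1006 in the knockout). The split was 696 against 645 and 783 against 778 with a floor of log2 8, 649 against 643 and 745 against 794 with 64 added, and 477 against 497 and 558 against 601 at 3-fold, so the direction of this imbalance depends on the setting. For the response difference (knockout minus wild type), positive against negative counts were 487 against 444 in the main setting and 541 against 382 with median centring. They were 335 against 209 with a floor of log2 8, 596 against 657 with no floor and 1189 against 1219 at 1.5-fold.

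The shared LPS effect (2823 genes) fell to 267 genes when fitted without genotype. The shared genotype effect passed for 893 of 9385 tested genes. It passed for 461 of 6331 with a floor of log2 8 and for 530 of 7819 with the mean of a gene's probe sets. Without LPS in the model it passed for 111 of 9385. Leaving out the other factor puts its effect into the residual spread. With the higher floor and with the mean of probe sets fewer genes were tested, and no further cause was tested. The knockout minus wild type difference of Kdm6b was 0.64 unstimulated and 0.85 with LPS on its second probe set, and 0 and -1.28 on the dimmest, against -0.51 and -0.41 on the brightest, and the cause was not tested. The median response difference of erythroid and megakaryocyte markers was -0.092 with all members and no floor against 0.89, where members below the floor entered. The labels pair no samples by animal or culture, so no analysis paired in that way was possible. The additive model compares the arrays within genotype and within LPS state. Leaving out a library leaves 0 residual degrees of freedom, so no test was run, and the effect then equals the difference in a single state. Between 32.1% and 34.5% of probe sets per array reached log2 6, and dimmer genes were not compared.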
